A study of Mus musculus with 18 samples.

How the data were processed

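The samples were pancreatic islets of 17-week-old male NOD.CB17-Prkdcscid mice of 3 Slc30a8 genotypes, untreated or cultured with 100 pg/ml TNF-α, 150 pg/ml IL-1β and 10 pg/ml IFN-γ for 24 h, with 3 libraries per group and 18 in all, per the labels. Islets were isolated by enzymatic digestion and gradient centrifugation, cultured overnight, and sequenced on an Illumina NovaSeq, per the labels' protocols. FastQC 0.11.7, cutadapt 1.16, STAR 2.5.2a, featureCounts 1.6.2 and DESeq2 1.30.0 with genome build GRCm38 are named, without roles or order, per the submitters' processing notes.

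The authors deposited raw read counts per gene in a table of 55536 genes, and the values are whole numbers whose totals run from 22990164 to 29946680 per library. A second deposited table holds the same counts for 25253 of these genes; the genes with reads that it leaves out were 8045, none of them protein coding, with 0.602% of the reads, when checked against the GENCODE M21 annotation. The authors also deposited a table of sample conditions with a replicate number, which was used only in an alternative chosen after seeing the data. Whether the library preparation kept strands is not given in the sources used here, so reads of overlapping genes on opposite strands, and of similar genes, are assigned with less certainty.

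From the full table, CPM values, log2 fold changes and p-values were computed here with R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and figures with Python 3.11.15 and matplotlib 3.10.9. Genes were kept by edgeR's filterByExpr with its count minimum of 10, which left 17590 genes, and libraries were scaled by TMM. A quasi-likelihood model with 1 mean per group was fitted to all 18 libraries, with 12 residual degrees of freedom and a median biological coefficient of variation of 0.106. There were 12 comparisons: cytokines against none in each genotype, the 3 pairs of genotypes in each treatment, and the 3 interactions. Adjusted p-values follow Benjamini and Hochberg over the genes tested, with a threshold of 0.05. In simulated data with 200 genes changed, the test for cytokines in WT islets recovered 50.7%, 62.3% and 84.4% of genes changed 1.5-, 2- and 4-fold, with 9 false among 139 calls on 17315 genes. The test for untreated KO against WT islets recovered 46.3%, 71.4% and 89.9%, with 5 false among 147 calls on 17298 genes, and the KO to WT interaction 23.1%, 42.9% and 78.1%, with 3 false among 99 calls. In the same 3 simulations DESeq2 made more false calls: 30 among 166, 26 among 176 and 18 among 127. There limma voom made about as few as edgeR: 9 among 137, 7 among 149 and 2 among 96.

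Lists of genes, 23 for processes and 11 for cell types, were tested by camera with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 34 lists within each comparison. Members were counted over all genes and adjusted over the list alone. In simulated data, 7 of 100 lists without a change had a camera p under 0.05. Lists share members: 10 of the beta cell genes, 5 of the nuclear oxidative phosphorylation genes and 3 of the NF-kB targets are also in another list, and none of the acinar, endothelial or mitochondrially encoded genes are.

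The named genes follow a rule. It takes Slc30a8 in each library, and in each comparison of cytokines, Het with WT and KO with WT, up to 10 higher and 10 lower genes with the largest change among those that passed, with a mean of at least 2 CPM and groups that do not overlap, without placeholder symbols. For KO with Het it takes up to 5 and 5, and for interactions up to 10 by smallest adjusted p or, where none passed, the 3 of smallest p. For each list it takes up to 4 members that passed, or up to 2 that did not, and fixed genes throughout, among them Ins1, Ins2, Gcg, Sst, Nos2, Mt1 and Mt2. Some genes that the rule names are not reported here. Groups, comparisons, lists, this rule and the main alternatives were chosen before the data were examined. The alternatives were RLE size factors, no low-count filter, the gene set of the authors' filtered table, a fit on only the groups compared, DESeq2, limma voom with sample quality weights, the replicate number as a block, and leaving out each library in turn. Alternatives chosen after seeing the data were the authors' metadata number as a block, marker levels of acinar cells or of 4 cell types as covariates, and leaving out the 2 libraries of lowest quality weight.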

Results

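RNA was sequenced from pancreatic islets of 17-week-old mice on the NOD.SCID background (NOD.CB17-Prkdcscid), which lack mature T and B lymphocytes. The mice were wild type (WT), heterozygous (Het) or knockout (KO) for Slc30a8. The gene encodes zinc transporter 8 (ZnT8), which moves zinc into insulin granules. After overnight culture, islets of each genotype were left untreated or given 100 pg/ml TNF-α, 150 pg/ml IL-1β and 10 pg/ml IFN-γ for 24 h, which makes 6 groups of 3 libraries. The deposited count table gave 22990164 to 29946680 reads assigned to genes per library, and 17590 of 55536 genes passed the low-count filter. The series title links a reduced ZnT8 dose to beta cell function and mitochondrial respiration, so genes of oxidative phosphorylation are reported for each genotype comparison. Levels are in CPM, counts scaled to the library size, as mean ± SD with n = 3, and changes are log2 fold changes ± SE from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The labels do not say whether the 3 libraries of a group, or libraries of both treatments, came from separate mice, so p-values measure the spread between these samples.

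Slc30a8 (ENSMUSG00000022315; GRCm38 chromosome 15, 52295553 to 52335798, plus strand) was read first, as a check of the genotype labels. It stood at 116 ± 14.5 CPM in untreated WT, 111 ± 15.2 CPM in untreated Het and 49.2 ± 6.07 CPM in untreated KO islets. With cytokines it stood at 41.5 ± 6.27 CPM in WT, 41 ± 13.5 CPM in Het and 21.4 ± 1.68 CPM in KO islets. The untreated libraries held 98.8, 123 and 125 CPM in WT, 126, 95.7 and 111 CPM in Het and 47.9, 55.9 and 44 CPM in KO. With cytokines they held 34.5, 43.7 and 46.4, then 32.1, 34.3 and 56.6, then 20.8, 23.2 and 20 CPM. The gene was lower in KO than in WT islets, at -1.23 ± 0.19 untreated (edgeR adjusted p = 0.00495) and -0.96 ± 0.20 with cytokines (adjusted p = 0.0148). The second call was lost without cytokine-treated KO replicate 1 (adjusted p = 0.0602) or 2 (0.0554) or WT replicate 2 (0.0664) or 3 (0.0522). Reads in KO stayed at 42.6% and 51.4% of the WT level. The part of the gene that is deleted is not given in the sources used here, and counts per gene do not separate reads inside it from reads outside it. Het islets did not differ from WT islets in Slc30a8, at -0.06 ± 0.19 untreated (edgeR adjusted p = 0.966) and -0.02 ± 0.19 with cytokines (adjusted p = 0.987). Alleles that add up would give -0.49 and -0.40. Intervals of 2 SE around the measured values reached from -0.44 to 0.32 and from -0.40 to 0.37, and without Het replicate 3 of the cytokine-treated islets (56.6 CPM) the second value was -0.32. Cytokines lowered Slc30a8 in all 3 genotypes, at -1.48 ± 0.19, -1.43 ± 0.19 and -1.21 ± 0.20 in WT, Het and KO islets.

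**Figure D1:**
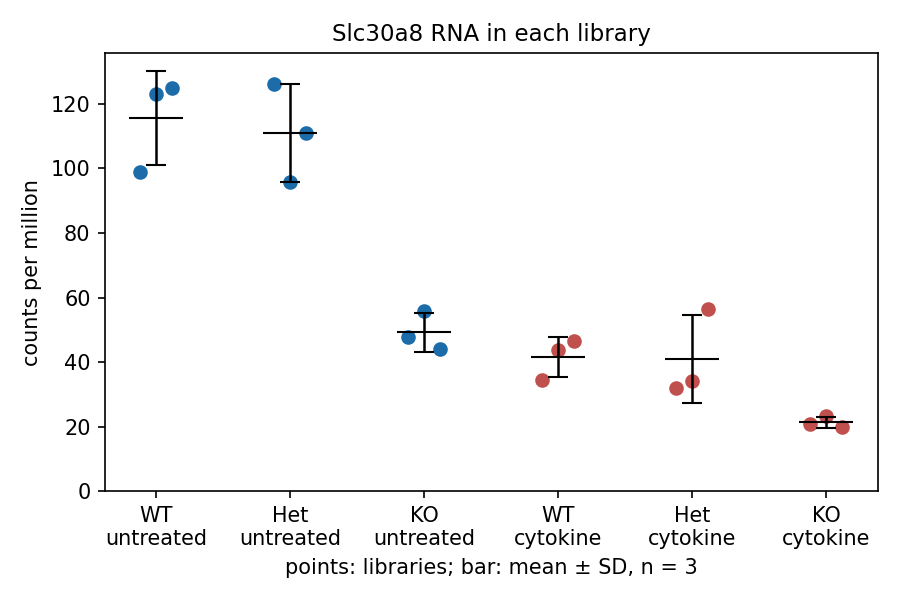
Slc30a8 RNA in CPM (vertical axis) for each of the 18 libraries, by genotype and treatment (horizontal axis); points are libraries and bars are the mean ± SD of 3. The KO libraries lie between 20 and 55.9 CPM, below the WT and Het libraries of the same treatment, and the Het libraries overlap the WT libraries.

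The first comparison asked what 24 h of cytokines did to islets of each genotype. Csf3, the granulocyte colony-stimulating factor gene, went from 0.656 ± 0.2 to 72.1 ± 2.99 CPM in WT islets (edgeR adjusted p = 2.50e-09), and rose by 6.78 ± 0.30, 7.54 ± 0.31 and 8.72 ± 0.34 in WT, Het and KO islets. The acute phase protein gene Orm1 rose by 6.63 ± 0.34, 7.29 ± 0.35 and 10.07 ± 0.44, and the neutrophil calprotectin gene S100a8 by 5.44 ± 0.53, 6.45 ± 0.58 and 9.06 ± 0.72. Serum amyloid Saa3 rose by 5.43 ± 0.39, 6.41 ± 0.42 and 8.14 ± 0.50. Nos2, the inducible nitric oxide synthase, rose from 1.51 ± 1.22 to 62.3 ± 1.6 CPM in WT, and to 66.1 ± 11 CPM in Het and 72.4 ± 15.5 CPM in KO islets (5.34 ± 0.49, 6.77 ± 0.55 and 7.82 ± 0.60). Untreated libraries held 84, 22 and 20 Nos2 reads in WT, 10, 5 and 37 in Het and 1, 2 and 23 in KO. The size of its rise thus rests on untreated levels near the floor. S100a8 was lower in untreated KO than in untreated WT islets, as reported below, and its larger rise in KO holds that untreated difference. By edgeR the responses of Csf3, Orm1, S100a8, Saa3 and Nos2 were not called different between genotypes. The glucose transporter gene Slc2a2 fell from 113 ± 17.8 to 15.5 ± 0.779 CPM in WT islets (edgeR adjusted p = 2.17e-06), with -2.87 ± 0.25, -2.93 ± 0.25 and -3.08 ± 0.25 in WT, Het and KO islets.

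In all, edgeR called 4515 genes in WT (2207 higher and 2308 lower), 4305 in Het (2240 and 2065) and 5504 in KO islets (2683 and 2821). Of these, 1140, 1165 and 1450 changed at least 2-fold. The groups did not overlap for 4460, 4040 and 5317 of the called genes, which were called from the same libraries. Among all genes tested, called or not, they did not overlap for 46.5%, 35.1% and 42.6%, against 10% by chance for 3 libraries against 3. The same 1521 genes rose and 1318 fell in all 3 genotypes. WT and Het shared 1627 higher and 1423 lower calls, where independent lists would share 281 and 271. WT and KO shared 1809 and 1777, against 337 and 370 for independent lists, and Het and KO 1841 and 1618, against 342 and 331. With only the 2 groups compared in the fit, 2461 genes passed in Het islets.

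Further genes with the largest increases in WT islets were the chemokines Cxcl5 (6.34 ± 0.70), Cxcl3 (5.83 ± 0.51) and Cxcl1 (5.49 ± 0.45), the matrix metalloproteinase Mmp3 (6.56 ± 0.86), the pantetheinase Vnn3 (6.00 ± 0.35) and Orm2 (5.68 ± 0.48). In Het islets Vnn3 (7.75 ± 0.41), the metalloreductase Steap4 (6.55 ± 0.55), the amino acid transporter Slc6a14 (6.60 ± 0.31), Cxcl5 (6.42 ± 0.70) and the IL-36 family cytokine Il1f6 (5.99 ± 0.39) stood in that place. In KO islets they were Slc6a14 (10.01 ± 0.42), lactotransferrin Ltf (9.31 ± 1.28), S100a9 (8.87 ± 1.00), Il1f6 (8.48 ± 0.52), Steap4 (8.37 ± 0.63) and Orm2 (8.27 ± 0.58). Of these, S100a9 and Steap4 were lower in untreated KO than in untreated WT islets, as reported below. Untreated, Slc6a14 stood at 0.038 ± 0.0408 CPM in KO and 0.955 ± 0.541 CPM in WT islets. Such low untreated levels enter the size of a rise. Among the largest decreases, Wnt4, a secreted Wnt ligand, fell by -3.18 ± 0.22, -3.20 ± 0.21 and -3.25 ± 0.21 in WT, Het and KO islets, and the calcium-binding protein gene Necab2 by -3.47 ± 0.23, -2.93 ± 0.22 and -3.14 ± 0.22. Ucn3, a peptide of mature beta cells, fell by -3.10 ± 0.28, -2.78 ± 0.27 and -3.21 ± 0.28, and the Wnt inhibitor Sfrp5 by -2.93 ± 0.32, -2.93 ± 0.31 and -3.24 ± 0.31. Zdhhc22, a palmitoyltransferase, fell by -2.66 ± 0.38, -3.33 ± 0.40 and -3.43 ± 0.37, and the pericyte and fibroblast antigen Cd248 by -2.55 ± 0.53, -3.09 ± 0.54 and -2.78 ± 0.52. Elastin Eln fell in Het islets (-3.69 ± 0.93), the collagen X gene Col10a1 and the insulin receptor-related gene Insrr in WT islets (-3.71 ± 0.47 and -2.36 ± 0.23), and the glycosyltransferase Extl1 in KO islets (-2.86 ± 0.22).

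**Figure D2:**
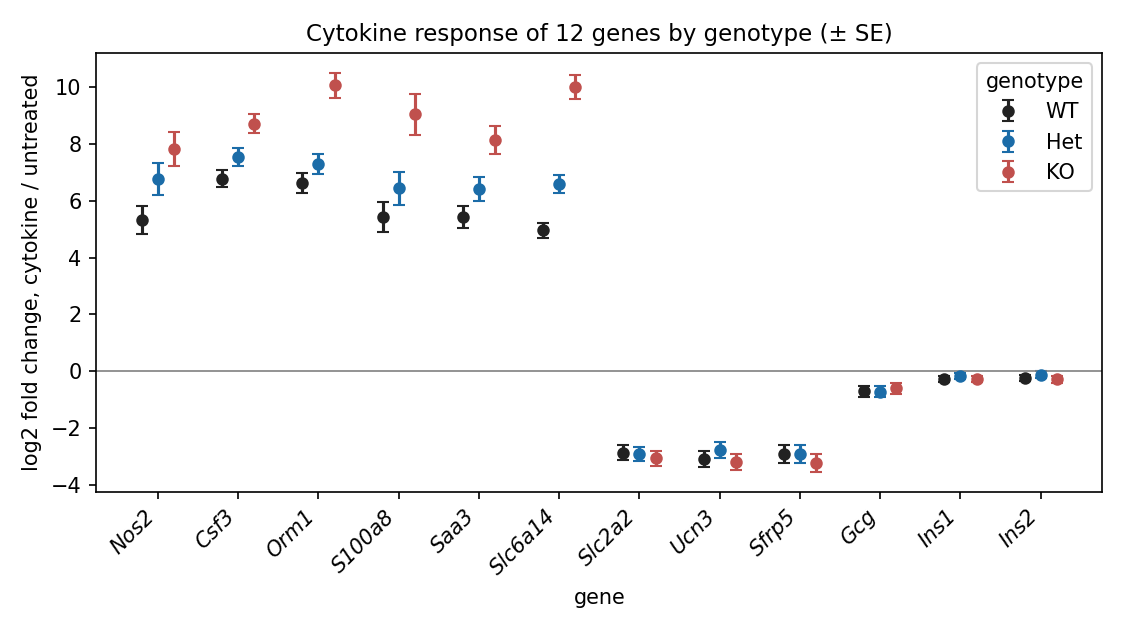
Log2 fold change of 12 genes with cytokines (vertical axis) for each gene (horizontal axis) in WT, Het and KO islets; points are edgeR estimates and bars their SE, with 3 libraries per group. Csf3, Orm1, S100a8, Saa3, Slc6a14 and Nos2 lie above 0 and Slc2a2, Ucn3, Sfrp5 and Gcg below 0 in each genotype, while Ins1 and Ins2 passed the threshold in none.

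NF-kB target genes rose together. Of 41 tested, 37, 33 and 35 rose in WT, Het and KO islets and none fell (39, 35 and 36 adjusted over the list alone), with median changes of 2.14, 1.99 and 1.98. The mitochondrial superoxide dismutase Sod2 rose by 2.26 ± 0.09, 2.68 ± 0.09 and 2.92 ± 0.09, the NF-kB regulator Nfkbiz by 1.71 ± 0.09, 2.05 ± 0.10 and 2.21 ± 0.10, and the receptor Tlr2 by 1.49 ± 0.09, 1.83 ± 0.09 and 1.85 ± 0.09. The camera set test called the list higher in each genotype (adjusted p = 3.24e-52, 4.64e-52 and 1.80e-49). These calls were lost with adjusted p = 0.063, 0.0628 and 0.0695 with an estimated correlation. Of 55 interferon targets 15, 20 and 24 rose and 0, 1 and 1 fell (15, 22 and 27 higher and 0, 1 and 2 lower adjusted over the list alone). Camera called that list higher in each genotype (adjusted p = 5.71e-06, 3.04e-06 and 4.92e-09, and adjusted p = 0.952, 0.954 and 0.894 with an estimated correlation). The guanylate-binding protein gene Gbp6 rose by 2.59 ± 0.22, 2.84 ± 0.22 and 3.62 ± 0.23, and Gbp10 by 4.64 ± 0.38 in Het and 4.23 ± 0.37 in KO islets. Genes of MHC class I presentation were higher for 10, 13 and 14 of 23 (14, 15 and 17 adjusted over the list alone). Among them were the immunoproteasome subunit Psmb10 (0.70 ± 0.11, 1.06 ± 0.11 and 1.14 ± 0.11) and the peptide-loading factor Tapbp (0.68 ± 0.10, 0.98 ± 0.10 and 1.04 ± 0.10). Camera gave adjusted p = 5.71e-06, 2.04e-08 and 1.95e-07 for that list, and adjusted p = 0.619, 0.676 and 0.894 with an estimated correlation.

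Beta cell genes changed in both directions. Of 44 genes of beta cell identity and insulin secretion, 7, 9 and 10 rose and 18, 13 and 18 fell in WT, Het and KO islets (9, 11 and 11 higher and 21, 15 and 20 lower adjusted over the list alone). Besides Slc2a2 and Ucn3, the oxidase gene of proinsulin folding Ero1lb fell by -1.17 ± 0.11, -1.13 ± 0.11 and -1.19 ± 0.11, and the beta cell transcription factor Mafa fell by -2.26 ± 0.23 in WT islets. Chgb, a granule protein gene, rose by 1.01 ± 0.11 in Het and 1.13 ± 0.11 in KO islets. Camera placed the list lower in WT (adjusted p = 5.11e-04) and KO islets (adjusted p = 0.0229), with adjusted p = 0.952 and 0.916 with an estimated correlation. It gave adjusted p = 0.331 in Het islets. The insulin genes Ins1 and Ins2 did not pass in any genotype. Ins2 stood at 112000 ± 9140 and 94400 ± 6430 CPM in WT islets without and with cytokines (-0.24 ± 0.12, -0.12 ± 0.12 and -0.29 ± 0.12 in WT, Het and KO islets), and Ins1 at 49200 ± 4020 and 40600 ± 2170 CPM (-0.28 ± 0.11, -0.16 ± 0.11 and -0.28 ± 0.11). Glucagon, Gcg, fell by -0.71 ± 0.19, -0.72 ± 0.19 and -0.61 ± 0.19, from 13400 ± 2410 to 8200 ± 1230 CPM in WT islets. Of 14 alpha cell genes, 8, 8 and 7 fell and none rose (9, 10 and 8 adjusted over the list alone), the thyroxine carrier transthyretin, Ttr, by -1.42 ± 0.23, -1.51 ± 0.23 and -1.70 ± 0.23. Camera called the alpha cell list lower in WT, Het and KO islets (adjusted p = 0.00423, 0.00267 and 0.0103, and adjusted p = 0.945, 0.93 and 0.894 with an estimated correlation). Somatostatin, Sst, fell by -0.54 ± 0.16 in WT and -0.47 ± 0.16 in KO islets and stood at -0.40 ± 0.16 in Het islets, where it did not pass.

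Proliferation genes were lower for 3, 20 and 14 of 27 in WT, Het and KO islets (3, 26 and 19 adjusted over the list alone), and the cyclin genes Ccnd1 (-0.85 ± 0.16, -0.86 ± 0.15 and -0.90 ± 0.16) and Ccnd2 (-0.65 ± 0.11, -0.60 ± 0.11 and -0.80 ± 0.11) fell in each. The list had camera adjusted p = 0.00278, 3.22e-06 and 1.51e-04, and adjusted p = 0.952, 0.93 and 0.894 with an estimated correlation. Genes of stellate and mesenchymal cells moved with them: 4, 10 and 4 of 19 fell (3, 13 and 4 adjusted over the list alone), the matrix Gla protein gene Mgp by -1.95 ± 0.27, -2.52 ± 0.28 and -2.77 ± 0.29. The mesenchymal list had camera adjusted p = 0.05, 1.49e-04 and 0.0118, and adjusted p = 0.952, 0.93 and 0.916 with an estimated correlation. NRF2 and antioxidant genes rose for 11, 12 and 12 of 28 and fell for 4, 4 and 3 (15, 14 and 13 higher and 4, 7 and 3 lower adjusted over the list alone). Among them were peroxiredoxin Prdx1 (1.05 ± 0.09, 0.92 ± 0.09 and 1.11 ± 0.09), thioredoxin Txn1 (0.67 ± 0.06, 0.65 ± 0.06 and 0.84 ± 0.06) and glutathione reductase Gsr (0.59 ± 0.05, 0.76 ± 0.05 and 0.65 ± 0.05). Its camera calls (adjusted p = 2.23e-06, 8.31e-06 and 8.00e-05) were lost with adjusted p = 0.063, 0.0843 and 0.153 with an estimated correlation.

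Nuclear genes of oxidative phosphorylation shifted by small amounts. Of 78, 15, 10 and 26 rose and 2, 2 and 3 fell in WT, Het and KO islets (14, 8 and 26 higher and 2, 1 and 3 lower adjusted over the list alone), with median changes of 0.06, 0.04 and 0.10. The cytochrome oxidase subunit Cox5a rose by 0.60 ± 0.07, 0.56 ± 0.07 and 0.72 ± 0.07. Camera called the list in KO islets (adjusted p = 0.0103, and adjusted p = 0.916 with an estimated correlation), with adjusted p = 0.078 in WT and 0.355 in Het islets. Of the 13 mitochondrially encoded genes 0 passed edgeR in any genotype, also adjusted over the list alone. In WT, Het and KO islets 0, 1 and 0 had an unadjusted p under 0.05, 0 passed DESeq2 and 0 limma, and the medians were 0.04, -0.07 and 0.09. Of the zinc genes, 5, 6 and 7 of 25 rose and 1, 0 and 2 fell (6, 6 and 9 higher and 1, 0 and 2 lower adjusted over the list alone). Camera called that list in no genotype (adjusted p = 0.175, 0.254 and 0.138). The zinc importer Slc39a6 rose by 0.37 ± 0.07, 0.46 ± 0.07 and 0.58 ± 0.07, the Golgi transporter Slc30a7 by 0.38 ± 0.06, 0.37 ± 0.06 and 0.49 ± 0.06, and the zinc-binding metallothionein Mt2 rose by 0.92 ± 0.15 in Het and 1.09 ± 0.15 in KO islets.

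The next comparison set Het against WT islets, the question the series title raises. The clearest difference lay in exocrine genes. The 30 acinar cell markers, which encode digestive enzymes and their partners, took 1.00% ± 0.00387 of the counts in untreated WT and 0.442% ± 0.0898 in untreated Het islets. With cytokines the shares were 1.03% ± 0.32 and 0.408% ± 0.0963. The carboxypeptidase Cpb1 stood at -1.35 ± 0.28 and ribonuclease Rnase1 at -1.30 ± 0.27 untreated, and the lectin Zg16 at -1.55 ± 0.26 with cytokines, without passing over all genes. By edgeR 0 of 30 passed over all genes and 27 and 28 were lower adjusted over the list alone. Of these markers 27 and 28 had an unadjusted p under 0.05, 14 and 24 passed DESeq2 and 0 and 17 passed limma. Camera called the acinar list lower in Het islets (medians -1.27 and -1.44, adjusted p = 1.83e-59 and 8.69e-69), also with adjusted p = 0.0451 and 0.0265 with an estimated correlation. Metallothioneins lay in the same direction, Mt1 at 533 ± 47.5 CPM in untreated WT and 295 ± 21.2 CPM in untreated Het islets (-0.85 ± 0.17, edgeR adjusted p = 0.236). Mt2 stood at 365 ± 46.1 and 213 ± 22.2 CPM (-0.78 ± 0.15, adjusted p = 0.191). Of 25 zinc genes 0 passed over all genes in either treatment. Adjusted over the list alone, 1 higher and 4 lower untreated and 2 lower with cytokines passed (7 and 5 had an unadjusted p under 0.05, 2 and 1 passed DESeq2 and 0 and 1 limma).

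Genes of mitochondrial respiration did not pass one by one between Het and WT islets. Of the 78 nuclear genes of oxidative phosphorylation 0 passed edgeR in either treatment, also adjusted over the list alone. Of them 4 and 1 had an unadjusted p under 0.05, 0 passed DESeq2 and 0 limma. Among the smallest p were those of the ATP synthase subunit Atp5e (0.22 ± 0.09) and the complex II subunit Sdhd (0.15 ± 0.05) untreated, and of Atp5g2 (0.10 ± 0.05) with cytokines. The list's median was 0.03 untreated (camera adjusted p = 0.00443, and adjusted p = 0.825 with an estimated correlation) and 0.02 with cytokines (adjusted p = 0.308). The 13 mitochondrially encoded genes all had positive estimates in Het islets in both treatments, with medians of 0.29 and 0.18 (camera adjusted p = 3.34e-07 and 0.00171, and adjusted p = 0.825 and 0.818 with an estimated correlation). Of these, 0 passed edgeR, also adjusted over the list alone (2 and 0 had an unadjusted p under 0.05, 0 passed DESeq2 and 0 limma). The complex I subunit mt-Nd1 stood at 0.33 ± 0.14 and 0.26 ± 0.14. The 44 beta cell genes had a median of 0.15 with cytokines (camera adjusted p = 4.57e-11, and adjusted p = 0.729 with an estimated correlation), and 0.02 untreated (adjusted p = 0.515). Of them 0 passed edgeR, also adjusted over the list alone (2 and 4 had an unadjusted p under 0.05, 0 passed DESeq2 and 0 limma). The pyruvate carboxylase Pcx stood at 0.30 ± 0.12 and Ins2 at 0.02 ± 0.12 and 0.14 ± 0.12.

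Over all genes, edgeR called 1 gene between untreated Het and WT islets. Crct1, a cornified envelope protein gene, stood at 1.19 ± 0.224 CPM in Het and 3.15 ± 0.667 CPM in WT islets (-1.41 ± 0.18, edgeR adjusted p = 0.0206). It did not pass with only the 2 groups in the fit (adjusted p = 0.253), with the replicate block by replicate number (0.0804), title number (0.143) or metadata number (0.0778), with 4 marker levels as covariates (0.742), or without WT replicate 1 (0.151), WT replicate 2 (0.0571), Het replicate 2 (0.145) or Het replicate 3 (0.213) of the untreated islets. With cytokines edgeR called 0 genes, where 1237 had an unadjusted p under 0.05 (1226 untreated), DESeq2 called 57 (47 untreated) and limma voom with quality weights 102 (2 untreated).

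Set against WT, KO islets differed more widely, and most called genes were lower. Acinar genes led again. Their share of the counts was 0.232% ± 0.0586 in untreated and 0.172% ± 0.0655 in cytokine-treated KO islets, against 1.00% and 1.03% in WT islets. Of the 30, 27 and 28 fell untreated and with cytokines (29 and 29 lower and 1 and 1 higher adjusted over the list alone). Zg16 fell by -2.42 ± 0.28 and -2.92 ± 0.29 untreated and with cytokines, the trypsinogen Try4 by -2.31 ± 0.30 and -2.86 ± 0.31, and Cpb1 by -2.28 ± 0.29 and -2.72 ± 0.30. Camera called the list lower (medians -2.22 and -2.68, adjusted p = 1.11e-74 and 1.37e-82), also with adjusted p = 0.0183 and 0.0123 with an estimated correlation. The acinar list in Het and KO islets against WT was the only list whose camera call held with an estimated correlation in any comparison of this study.

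**Figure D3:**
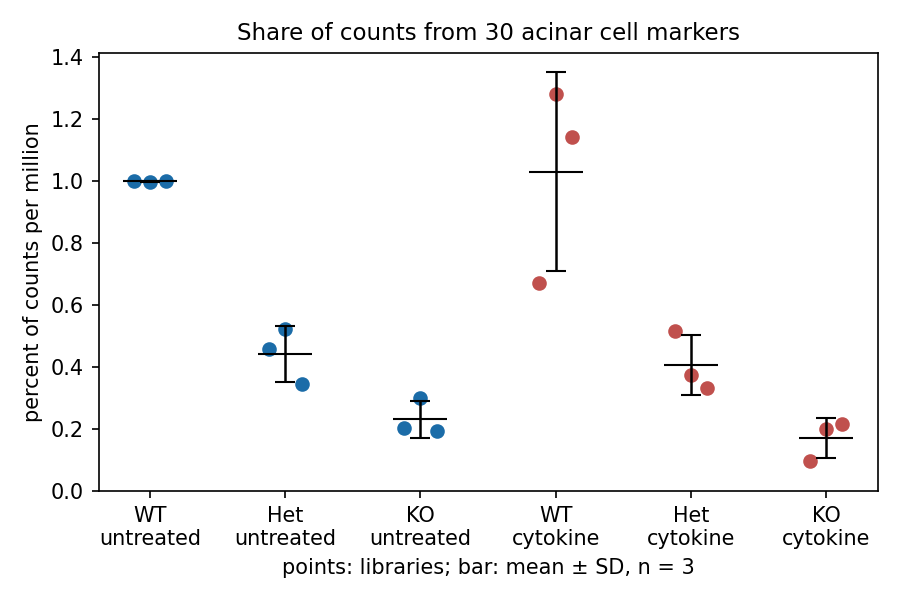
Percent of the counts that came from the 30 acinar cell markers (vertical axis) in each library, by genotype and treatment (horizontal axis); points are libraries and bars the mean ± SD of 3. WT libraries lie between 0.67% and 1.28%, Het libraries between 0.333% and 0.522% and KO libraries between 0.0967% and 0.3%.

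Other cell types moved with the genotype to different degrees. Of 14 duct cell genes 5 and 5 fell in KO islets untreated and with cytokines (5 and 6 adjusted over the list alone), the trefoil peptide Tff2 by -2.31 ± 0.31 and -3.03 ± 0.32 and keratin Krt18 by -0.94 ± 0.15 and -1.06 ± 0.15. Of 15 endothelial genes 2 and 5 fell (10 and 13 adjusted over the list alone), the VEGF receptor Kdr by -1.09 ± 0.19 and -1.05 ± 0.19. Camera gave adjusted p = 1.49e-09 and 1.59e-09 for duct genes (adjusted p = 0.264 and 0.374 with an estimated correlation) and 1.12e-09 and 6.97e-12 for endothelial genes (adjusted p = 0.409 and 0.437 with an estimated correlation). With the endothelial marker level as a covariate, chosen after seeing the data, the mean of the duct list went from -0.85 ± 0.31 to -0.33 ± 0.32 untreated and from -1.02 ± 0.31 to -0.33 ± 0.36 with cytokines. With the acinar level it was -0.80 ± 0.71 and -0.96 ± 0.84, with the mesenchymal level -0.92 ± 0.19 and -0.88 ± 0.19, and with the macrophage level -1.13 ± 0.30 and -1 ± 0.27. Of 19 mesenchymal genes 0 passed edgeR in either treatment, also adjusted over the list alone, with medians of 0.29 and -0.04 (1 and 2 had an unadjusted p under 0.05, 1 and 2 passed DESeq2 and 1 and 0 limma). Rgs5, a pericyte gene, stood at -0.62 ± 0.17 and -0.54 ± 0.18. Among macrophage genes the integrin Itgax rose in untreated KO islets (1.04 ± 0.23, edgeR adjusted p = 0.0257). It was 1 of 21 genes (4 higher adjusted over the list alone; camera adjusted p = 7.41e-07, and adjusted p = 0.499 with an estimated correlation). The macrophage genes' share of the counts was 0.0584% in untreated KO replicate 3, against 0.0221% and 0.0235% in the other 2 untreated KO libraries and 0.023% to 0.0271% in untreated WT libraries. That library also held the highest untreated shares of lymphocyte genes (0.00197%) and mesenchymal genes (0.507%), and without it Itgax did not pass (0.78, adjusted p = 0.0819).

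Among the genes that fell most in untreated KO against untreated WT islets, the calprotectin genes S100a9 and S100a8 fell by -4.38 ± 0.96 and -3.58 ± 0.89, Steap4 by -2.63 ± 0.65 and the acute phase glycoprotein Lrg1 by -2.44 ± 0.57. Hamp, which encodes the iron hormone hepcidin, fell by -3.60 ± 0.45, from 4.92 ± 2.76 to 0.401 ± 0.202 CPM (edgeR adjusted p = 0.00215). Of 41 NF-kB targets 8 fell and none rose (13 lower adjusted over the list alone), among them Nfkbiz (-0.48 ± 0.09), the apoptosis inhibitor Birc3 (-0.80 ± 0.18) and lipocalin Lcn2 (-1.80 ± 0.39). Camera called the list lower (median -0.41, adjusted p = 1.98e-11, and adjusted p = 0.463 with an estimated correlation). Of 55 interferon targets 1 fell and none rose (1 lower adjusted over the list alone; camera adjusted p = 5.83e-05, and adjusted p = 0.732 with an estimated correlation). With cytokines 1 NF-kB target rose, Sod2 (0.38 ± 0.09), and 1 fell, the chemokine Cxcl2 (-1.23 ± 0.33), and camera called no shift (median -0.11, adjusted p = 0.35; 1 passed adjusted over the list alone). Immediate early genes, such as the transcription factor genes Klf4 (-0.74 ± 0.10 and -0.52 ± 0.10 untreated and with cytokines) and Atf3 (-0.63 ± 0.12 and -0.55 ± 0.12), fell for 5 and 2 of 21 (9 and 2 adjusted over the list alone). Camera gave adjusted p = 1.17e-08 and 2.60e-05 for them, and adjusted p = 0.264 and 0.542 with an estimated correlation. With the endothelial marker level as a covariate, the mean of the NF-kB list went from -0.68 ± 0.29 to -0.15 ± 0.27 untreated and from -0.26 ± 0.29 to 0.45 ± 0.30 with cytokines. That of the immediate early list went from -0.34 ± 0.14 to -0.05 ± 0.12 untreated and 0.06 ± 0.13 with cytokines. Untreated, the NF-kB list stood at -1.43 ± 0.60 with the acinar, -0.74 ± 0.22 with the mesenchymal and -1.05 ± 0.20 with the macrophage level as a covariate, and the immediate early list at -0.44 ± 0.32, -0.37 ± 0.07 and -0.51 ± 0.11.

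Zinc genes changed in both directions in KO islets. Metallothionein Mt1 fell by -1.09 ± 0.17, from 533 ± 47.5 to 251 ± 18 CPM, and Mt2 by -1.13 ± 0.15, and Mt3 rose by 1.06 ± 0.17, from 5.06 ± 0.771 to 10.5 ± 1.48 CPM (edgeR adjusted p = 0.00476). With cytokines Mt3 rose by 1.12 ± 0.18 and Mt1 fell by -0.70 ± 0.17 (adjusted p = 0.0285). The vesicle zinc transporter Slc30a2 fell by -1.84 ± 0.39 and -2.91 ± 0.43 untreated and with cytokines, and with cytokines its relative Slc30a3 fell by -3.76 ± 0.66 and the importer Slc39a5 by -3.07 ± 0.53. Acinar markers fell in the same samples, and with their level as a covariate Slc30a2 turned to 0.81 and 0.29, and Mt1 moved to -0.34 untreated and turned to 0.22 with cytokines. In all 3 rose and 6 fell of 25 untreated (3 and 9 adjusted over the list alone; camera adjusted p = 0.0143, and adjusted p = 0.264 with an estimated correlation). With cytokines 1 rose and 4 fell (2 and 6 adjusted over the list alone; adjusted p = 0.186). Of 51 neighbours of Slc30a8 on chromosome 15, 3 fell untreated, and 1 rose and 2 fell with cytokines (2 and 1 higher and 7 and 3 lower adjusted over the list alone). The cytoskeletal adaptor Sntb1 fell by -0.81 ± 0.17 untreated, and the list had camera adjusted p = 0.686 and 0.86.

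Some beta cell genes were higher in KO islets. The phosphatase regulator Ppp1r1a rose in untreated KO islets (0.67 ± 0.16), and the proinsulin convertase Pcsk1 (0.46 ± 0.11), the glucose-6-phosphatase G6pc2 (0.49 ± 0.11) and the SNARE protein Snap25 (0.50 ± 0.12) rose with cytokines. That was 1 and 3 of 44 genes (7 and 13 higher and 1 and 0 lower adjusted over the list alone), with medians of 0.25 and 0.26, camera adjusted p = 2.76e-10 and 3.22e-12, and adjusted p = 0.498 and 0.542 with an estimated correlation. With the endothelial marker level as a covariate the list's mean went from 0.25 ± 0.11 to 0.04 ± 0.09 untreated and from 0.29 ± 0.11 to 0 ± 0.11 with cytokines, and with the acinar level it was 0.46 ± 0.24 and 0.53 ± 0.28. With the mesenchymal level it was 0.28 ± 0.07 and 0.24 ± 0.07, and with the macrophage level 0.38 ± 0.09 and 0.28 ± 0.08. Ins2 did not pass, at 0.26 ± 0.12 and 0.22 ± 0.12, and turned to -0.12 and -0.30 with 4 marker levels as covariates. Of the 78 nuclear genes of oxidative phosphorylation, the ATP synthase subunit Atp5l rose untreated (0.32 ± 0.07) and 0 passed edgeR with cytokines, where 26 had an unadjusted p under 0.05, 9 passed DESeq2 and 23 limma (1 and 0 adjusted over the list alone). Their medians were 0.04 and 0.08, with camera adjusted p = 0.00473 and 4.58e-06, and adjusted p = 0.766 and 0.716 with an estimated correlation. The 13 mitochondrially encoded genes had medians of 0.19 and 0.33 (camera adjusted p = 0.0132 and 2.57e-04, and adjusted p = 0.732 and 0.648 with an estimated correlation). By edgeR 0 of them passed, also adjusted over the list alone (0 and 5 had an unadjusted p under 0.05; 0 and 1 passed DESeq2 and 0 and 1 limma).

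By the size of the change, the amylase Amy2b (-2.46 ± 0.36), the chymotrypsin-like protease Ctrl (-2.39 ± 0.35), the disulfide isomerase Pdia2 (-2.38 ± 0.35) and the lipase Pnlip (-2.36 ± 0.41) completed the genes that fell most in untreated KO islets. With cytokines they were Prss3 (-3.17 ± 0.82), the trefoil peptide Tff1 (-3.17 ± 0.76), the keratins Krt20 (-3.11 ± 0.58) and Krt6a (-3.08 ± 0.62), the lectin Reg3a (-3.06 ± 0.47), Tff2, Ctrl (-3.01 ± 0.36), Zg16, the phospholipase Pla2g1b (-2.87 ± 0.38) and Try4. The trypsinogens Prss3 and Try4 belong to a family of similar genes, so their reads are not certain to be their own. Among the largest increases untreated were the membrane adaptor Bin2 (1.98 ± 0.50), the mucus glycoprotein Olfm4 (0.97 ± 0.16), the NADPH oxidase subunit Cybb (0.93 ± 0.23), tyrosine hydroxylase Th (0.85 ± 0.19) and the prolactin receptor Prlr (0.73 ± 0.16). With cytokines they included the collagen receptor Lair1 (0.99 ± 0.26), Wfdc16 (0.98 ± 0.20), the transglutaminase Tgm3 (0.89 ± 0.19) and Th (0.86 ± 0.21). With the acinar level as a covariate Pdia2 turned to 0.04 untreated and Krt6a to 0.11 and Tff1 to 0.97 with cytokines. With 4 marker levels Amy2b turned to 0.27, Pnlip to 0.51 and Bin2 to -0.67 untreated, Pla2g1b to 0.05 with cytokines and Th to -0.01 and -0.32. Amy2b, Pnlip and Pla2g1b are themselves among the acinar markers of that fit, which takes out their own difference.

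By edgeR, 517 genes differed between untreated KO and WT islets (94 higher and 423 lower; 11 and 145 by at least 2-fold) and 937 with cytokines (268 and 669; 8 and 234 by at least 2-fold). The groups did not overlap for all 517 and for 934 of the 937. These genes were called from the same libraries, so their lack of overlap is no further evidence. Among all genes tested, called or not, the groups did not overlap for 25.7% and 30.5%, against 10% by chance. Both treatments shared 18 higher and 226 lower calls, where independent lists would share 1.43 and 16.1. Of the 517 genes 495, and of the 937 genes 929, had the same sign between Het and WT islets (95.7% and 99.1%), at a median ratio of 0.42 and 0.47 of the KO change. Het and KO were set against the same WT libraries, which alone gives shared signs. In 20 simulations of unchanged groups, as many genes of smallest KO p had the same sign for 92.6% and 90.7% (highest 94.6% and 92.2%), at a median ratio of 0.50 and 0.50. The observed shares lay above these. The simulated genes carried no change, unlike genes that passed the threshold. The simulated share is thus not the part of the observed agreement that came from shared controls. Over all genes their fold changes correlated at 0.41 untreated and 0.70 with cytokines, where these simulations gave means of 0.50 and 0.51 and highest values of 0.53 and 0.54. The same sign was seen for 64.7% and 78.6% of genes, against 66.8% and 66.9% simulated. The simulations used 1 spread per gene for all groups. Untreated WT libraries differed less from each other (chi-square over genes per degree of freedom 7 to 10.8) than untreated Het libraries (16.9 to 53.5). For untreated islets these measures therefore cannot decide whether Het and KO changes went together beyond the shared controls. The fold changes had a covariance of 0.0631 untreated and 0.101 with cytokines, where the shared controls alone gave 0.0478 and 0.0492 (highest 0.0523 and 0.0537). The differences of 0.0153 and 0.0514 estimate the part not from the controls only as far as that simulated spread holds. The WT libraries were also divided 1 against 2, so that Het and KO had different controls, an alternative chosen after seeing the data. The covariance was then 0.0338 untreated (0.023 to 0.048 in 6 divisions) and 0.0609 with cytokines (0.0429 to 0.0757). Each untreated division lay above 0.0153, so the simulations may overstate what the shared controls gave there.

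DESeq2 called 927 genes untreated and 1548 with cytokines, limma voom with quality weights 1694 and 3990, and the fit on only the compared groups 581 with cytokines; 0 genes passed edgeR in either treatment with the acinar marker level as a covariate, an alternative chosen after seeing the data. Leaving out 1 library gave 118 (KO replicate 1), 194 (KO replicate 2), 361 (KO replicate 3), 128 (WT replicate 1), 298 (WT replicate 2) and 249 (WT replicate 3) untreated, and 374 (KO replicate 1), 205 (KO replicate 2), 1300 (KO replicate 3), 454 (WT replicate 1), 261 (WT replicate 2) and 559 (WT replicate 3) with cytokines.

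KO and Het islets were compared next. Slc30a8 stood at -1.17 ± 0.19 untreated (edgeR adjusted p = 0.112) and -0.94 ± 0.20 with cytokines (adjusted p = 0.34) and so did not pass over all genes, although the KO libraries lay below the Het libraries. Muc4, a membrane mucin, fell from 60.5 ± 7.59 to 39.9 ± 0.866 CPM with cytokines (-0.60 ± 0.08, edgeR adjusted p = 0.0459) and was the 1 gene called there (1463 had an unadjusted p under 0.05, 55 passed DESeq2 and 111 limma). Acinar genes lay lower in KO than in Het islets, with medians of -0.92 and -1.22. Of these 0 passed over all genes and 18 and 25 of 30 adjusted over the list alone (21 and 26 had an unadjusted p under 0.05, 7 and 12 passed DESeq2 and 5 and 13 limma). Camera gave adjusted p = 1.08e-18 and 2.22e-45, and adjusted p = 0.427 and 0.121 with an estimated correlation. Of the nuclear genes of oxidative phosphorylation 0 of 78 passed edgeR in either treatment, also adjusted over the list alone (5 and 13 had an unadjusted p under 0.05, 0 passed DESeq2 and 3 and 0 limma), with medians of 0.01 and 0.07. Atp5l stood at 0.20 ± 0.07 untreated. Their camera adjusted p was 0.483 untreated and 1.90e-09 with cytokines, with adjusted p = 0.942 with an estimated correlation for the latter. Untreated, edgeR called 0 genes, where 2564 had an unadjusted p under 0.05, DESeq2 called 309 and limma voom with quality weights 2149. Without untreated Het replicate 1, the library of lowest quality weight (0.231), edgeR called 1855 (765 higher and 1090 lower). The Muc4 call was lost with only the 2 groups in the fit (adjusted p = 0.548), with RLE size factors (0.0557), with the replicate block by replicate number (0.0545) or title number (0.116), with the acinar level (0.878) or 4 marker levels (0.647) as covariates, and without Het replicate 1 (0.0724), 2 (0.0536) or 3 (0.189) or KO replicate 1 (0.251), 2 (0.338) or 3 (0.0957) of the cytokine-treated islets.

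Whether the cytokine response itself differed between genotypes was tested as an interaction. Slc6a14, which carries neutral and basic amino acids, rose more in KO than in WT islets (difference of log2 fold changes 5.05 ± 0.71, edgeR adjusted p = 0.0374). The difference lay in the untreated level, 0.955 ± 0.541 CPM in WT and 0.038 ± 0.0408 CPM in KO islets, while the level with cytokines was 30.2 ± 1.37 and 42.8 ± 2.31 CPM. Gm19680, a processed pseudogene, differed the other way (-2.40 ± 0.34, adjusted p = 0.0374). These were the 2 genes called between KO and WT, where 1184 had an unadjusted p under 0.05, DESeq2 called 52 and limma 26. Between Het and WT edgeR called 0 genes (842 with an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma) and between KO and Het 0 (1008, 1 and 0). The pyruvate dehydrogenase kinase Pdk3 at 0.38 ± 0.08 between Het and WT and the nucleotide kinase Cmpk1 at 0.40 ± 0.07 between KO and Het were among the smallest p, neither passing. NF-kB targets as a list had a median difference of 0.28 between KO and WT (camera adjusted p = 1.79e-08, and adjusted p = 0.92 with an estimated correlation). Over all genes 0 passed, and 14 higher and 1 lower adjusted over the list alone (16 had an unadjusted p under 0.05, 3 passed DESeq2 and 3 limma). The Slc6a14 call was lost with the gene set of the authors' filtered table (adjusted p = 0.0694), limma (0.0768), no low-count filter (0.0652), the replicate block by replicate number (0.165) or metadata number (0.101), the acinar level (0.0794) or 4 marker levels (0.148) as covariates, and without the 2 libraries of lowest quality weight (0.127). It was also lost without KO replicate 1 (0.139), 2 (0.13) or 3 (0.154) or WT replicate 1 (0.0945) or 2 (0.0529) of the untreated islets, and without KO replicate 1 (0.079), 2 (0.102) or 3 (0.0533) or WT replicate 1 (0.09), 2 (0.109) or 3 (0.099) of the cytokine-treated islets. The Gm19680 call was lost with the replicate block by replicate number (0.0835) or metadata number (0.0746) and with the acinar level (0.0794) or 4 marker levels (0.0707) as covariates. It was also lost without any 1 library of these groups but untreated WT replicate 3 (0.0447), with adjusted p from 0.0529 to 0.142.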

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

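The tests of the 3 patterns weighed here were chosen only after the results were seen, while the regroupings of libraries were planned. A pair of genes was flagged because the cytokine response differed between KO and WT islets by an interaction test: Slc6a14 by 5.05 and the processed pseudogene Gm19680 by -2.40. Slc6a14 had 0 to 2 reads per library in untreated KO, 6 to 18 in untreated Het and 14 to 45 in untreated WT islets, and 983 to 1153, 822 to 1220 and 697 to 805 with cytokines. Gm19680 had 20 to 32, 28 to 40 and 25 to 33 reads untreated and 9 to 10, 22 to 35 and 43 to 61 with cytokines. When the genotype labels were reassigned within each treatment, 6 of 100 regroupings gave as many genes as the real one's 2 (highest other 2663). Such a regrouping can exchange genotypes in the untreated or the cytokine-treated islets alone, which puts the genotype difference itself into the contrast. The regroupings therefore cannot decide whether chance gave these calls, and chance stays open.

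The first pattern is the set of genes lower in KO than in WT islets. A fall of all non-endocrine cells by the same amount does not hold for it, since the mesenchymal marker level moved apart from the acinar level by 2.22 ± 0.60. In untreated KO against WT islets, duct markers stood at -0.85 ± 0.31 and endothelial markers at -0.72 ± 0.28. Mesenchymal markers stood at 0.12 ± 0.44 and macrophage markers at 0.59 ± 0.36. An unequal loss of non-endocrine cells stays open. Fewer acinar cells go with the acinar markers, of which 29 of 30 had a negative change with an interquartile range of 0.21. The 396 lower genes off that list had a mean difference of -0.83 ± 0.08. It was -0.61 ± 0.16 with the acinar level as a covariate, where no single gene passed. These genes were called lower in the same samples, and the acinar level goes with genotype (-2.1 ± 0.31 in untreated KO against WT). The fit therefore cannot decide whether fewer acinar cells are the whole cause for these genes. Within groups their median correlation with the acinar level was 0.11, against 0.93 for the called acinar markers, and 18.4% of them lay over 0.5, against 4.47% of all genes, so a part from acinar cells stays open. A genotype effect on these genes, or on the acinar cells themselves, and a difference in islet purity between preparations were not tested and stay open.

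The second pattern is Slc30a8 RNA in Het islets at the WT level. Alleles that add up, with the mutant allele at its level in KO, would give -0.44 ± 0.04 over both treatments; the measured -0.04 ± 0.13 lies above that by 0.41 ± 0.14, but by 0.25 ± 0.13 without Het replicate 3 of the cytokine-treated islets, so adding alleles and a higher level cannot be told apart because 1 library decides it. A higher share of beta cells in the Het samples would raise the gene, and the beta cell list differed by 0.10 ± 0.08; that cannot be told apart from the needed 0.41 because both errors are large. A genotype effect, such as higher expression from the intact allele, was not tested and stays open.

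The third pattern is NF-kB targets lower in untreated KO than in untreated WT islets, at -0.68 ± 0.29 for the list mean. With the acinar marker level as a covariate the difference was -1.43 ± 0.60. That level goes with genotype and the error grew, so the fit cannot decide whether fewer acinar cells account for the pattern. Fewer endothelial cells go with it, since the difference was -0.15 ± 0.27 with the endothelial marker level as a covariate, though endothelial genes are themselves lower in the same samples and with cytokines the list turned from -0.26 ± 0.29 to 0.45 ± 0.30 in that fit. With the mesenchymal or macrophage level as a covariate the untreated difference was -0.74 ± 0.22 or -1.05 ± 0.20. A genotype effect on inflammation in the islets was not tested and stays open.

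The libraries of each pair of groups were also split in all 10 possible ways, and 10 splits are too few for a share under 0.05. For cytokines, 1 of 10 splits in WT, Het and KO islets gave as many genes as the real 4515, 4305 and 5504, and the highest other counts were 0, 182 and 0. For KO against WT it was 1 of 10 in both treatments (real 517 and 937, highest other 0 and 0). For Het against WT untreated it was 1 of 10 (real 1, highest other 0), and for KO against Het with cytokines 1 of 10 (real 1, highest other 0). Where the real count was 0, every split reaches it and the count says nothing on chance: 10 of 10 for Het against WT with cytokines (highest other 0) and KO against Het untreated (highest other 3254), and 100 of 100 regroupings for the interactions of Het with WT and KO with Het (highest other 70 and 2628). The count of 3254, far over the real 0, points to a structure of those samples other than the groups. Regroupings for the interactions can exchange genotypes in 1 treatment only, which puts the genotype difference itself into the contrast. The counts of 2628 and 2663 therefore cannot tell another structure from that difference.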

How the results depend on the processing

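The covariates, the block by the authors' metadata number and the fit without the 2 libraries of lowest quality weight were chosen only after the results were seen. The cytokine counts kept within 1.5 times their value under each alternative but the fit on only the groups compared, which gave 2461 in Het islets; the other counts moved as follows, and the cause was not tested unless named. Of the named genes' values, 2519 under the other alternatives and 1296 with a library left out kept their direction and side of the threshold, 210 and 189 lost the call, 37 and 8 gained it, and 30 and 7 changed sign.

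DESeq2 gave 47 and 57 genes for Het with WT, 927 and 1548 for KO with WT, 309 and 55 for KO with Het (untreated, then cytokines), 52 for the KO to WT interaction and 1 for KO to Het. limma voom with quality weights gave 2 and 102, 1694 and 3990, 2149 and 111, and 26 for the KO to WT interaction. Only the groups compared gave 0 and 1 for Het with WT, 581 for KO with WT with cytokines, 0 for KO with Het with cytokines and 6 for the KO to WT interaction. No low-count filter gave 2 for untreated Het with WT and 4 for the KO to WT interaction, RLE size factors 0 for KO with Het with cytokines, and the gene set of the authors' filtered table gave 0 for the KO to WT interaction. Without the 2 libraries of lowest quality weight the counts were 6 for untreated Het with WT, 1276 and 2031 for KO with WT, 3015 and 4 for KO with Het, and 4 and 64 for the KO to WT and KO to Het interactions.

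With the acinar marker level as a covariate 0 genes passed for untreated Het with WT, KO with WT in both treatments, KO with Het with cytokines and the KO to WT interaction; Slc30a8 between KO and WT went from -1.23 ± 0.19 to -1.27 ± 0.44 untreated and from -0.96 ± 0.20 to -1.01 ± 0.53 with cytokines, with adjusted p = 0.649 and 0.663. The covariate goes with genotype, so for this gene the calls ended with a wider error and not with a smaller fold. With 4 marker levels the counts were 0 for untreated Het with WT, 0 and 0 for KO with WT and 2 for KO with Het with cytokines.

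Leaving out 1 library gave 118 to 361 and 205 to 1300 genes for KO with WT, 0 to 2 and 0 to 2 for Het with WT, 0 to 1855 and 0 to 0 for KO with Het, and 0 to 2 and 0 to 4 for the KO to WT and KO to Het interactions, where fewer samples also lower the counts. The cytokine counts ran from 3368 to 3854, 3328 to 4092 and 4361 to 5136 in WT, Het and KO islets.

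With the replicate block, which assumes that equal numbers share a source, the counts were 0 and 2 for Het with WT, 0 for KO with Het with cytokines and 1 for the KO to WT interaction, which was neither Slc6a14 nor Gm19680. The replicate block by title number gave 0 for untreated Het with WT and 3 and 0 for KO with Het, and by the authors' metadata number 0 and 1 for Het with WT and 0 for the KO to WT interaction. Of 9 pairs of equal number, 6 deviated together with a correlation over 0.1. Among 3 candidates each, 12 of 18 libraries correlated best with their own number, more than picks at random would give. Libraries of equal number thus tended to go together, though not every pair did.

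Some values changed sign. Between Het and WT, Slc30a8 moved to 0.03 untreated and 0.05 with cytokines with the title-number block, to 0 with cytokines without the low-count filter, and ranged from -0.16 to 0.04 and -0.32 to 0.13 with a library left out. Ins2 moved to -0.01 untreated with limma and -0.06 without the 2 libraries of lowest weight, ranged from -0.06 to 0.09 with a library left out, and with 4 marker levels stood at -0.04 untreated and -0.02 with cytokines. With the acinar covariate, KO with WT values were 0.81 and 0.29 for Slc30a2 (untreated, then cytokines), 0.04 for Pdia2 untreated, and 0.11 for Krt6a, 0.22 for Mt1 and 0.97 for Tff1 with cytokines. With 4 marker levels they were 0.81 and 0.42 for Slc30a2, -0.12 and -0.30 for Ins2, -0.01 and -0.32 for Th, 0.27 for Amy2b, -0.67 for Bin2, 0.04 for Pdia2 and 0.51 for Pnlip untreated, and 0.05 for Acads, 0.34 for Mt1, 0.05 for Pla2g1b, 0.01 for Slc39a5 and 1.46 for Tff1 with cytokines. They were 0 for Atp5g2 between Het and WT with cytokines and -0.04 for Atp5l between KO and Het untreated. Amy2b, Pnlip and Pla2g1b are among the markers that make up the acinar level, so a fit with that level takes out their own difference. Camera with the acinar covariate likewise turned the acinar list, which that covariate is made of. The list had camera adjusted p = 0.709 and 0.978 for Het with WT and 0.905 and 0.994 for KO with WT. That camera test also turned nuclear oxidative phosphorylation genes in Het with WT with cytokines (0.267), untreated KO with WT (0.825) and untreated KO with Het (0.553), and mesenchymal genes in untreated KO with WT (0.114).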

Other observations

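The tests of list members below were planned, while the fit with 4 marker levels was chosen only after the results were seen. Stress and survival genes also changed with cytokines. Among 31 apoptosis regulators 14, 10 and 14 rose and 2, 4 and 4 fell in WT, Het and KO islets (15, 10 and 15 higher and 2, 5 and 4 lower adjusted over the list alone). The caspase inhibitor Birc3 rose by 2.67 ± 0.18, 3.20 ± 0.18 and 3.66 ± 0.19 and the pro-apoptotic gene Bbc3 fell by -1.09 ± 0.15, -1.40 ± 0.15 and -1.47 ± 0.15. Camera gave adjusted p = 3.15e-05, 0.0104 and 0.00168 for that list, and adjusted p = 0.619, 0.93 and 0.894 with an estimated correlation. Of 38 genes of the unfolded protein response, which restores protein folding in the endoplasmic reticulum, 8, 7 and 8 rose and 14, 13 and 14 fell (9, 7 and 9 higher and 14, 15 and 14 lower adjusted over the list alone). The glutathione-degrading enzyme gene Chac1 fell by -1.53 ± 0.13, -1.66 ± 0.13 and -1.97 ± 0.13, while Edem1, which clears misfolded glycoproteins, rose by 0.58 ± 0.05, 0.77 ± 0.05 and 0.83 ± 0.05. In KO against WT islets the stress regulator Nupr1 fell by -1.87 ± 0.32 and -2.28 ± 0.33 untreated and with cytokines.

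Some genes of energy metabolism changed with cytokines, in both directions. Over all genes tested, 25.7%, 24.5% and 31.3% changed in WT, Het and KO islets. Hif1a, the oxygen-sensing transcription factor, rose by 1.05 ± 0.08 in WT and 1.24 ± 0.08 in KO islets. In WT, Het and KO islets 5, 5 and 10 of 24 hypoxia target entries rose and 0, 1 and 1 fell (5, 5 and 11 higher and 0, 1 and 1 lower adjusted over the list alone). These entries cover 23 gene symbols, since Aldoa has separate entries under different gene IDs. Of 21 genes of fatty acid oxidation 3, 4 and 3 rose and 3, 5 and 4 fell (3, 5 and 3 higher and 4, 6 and 5 lower adjusted over the list alone). The pyruvate dehydrogenase kinase Pdk4 fell by -1.65 ± 0.19, -1.92 ± 0.19 and -1.81 ± 0.19 and the dehydrogenase Hadh, which restrains insulin secretion, by -1.09 ± 0.15, -1.02 ± 0.15 and -1.22 ± 0.15. Of 26 genes of the TCA cycle 5, 3 and 6 rose and 2, 2 and 1 fell (6, 2 and 6 higher and 2, 2 and 1 lower adjusted over the list alone), with medians of -0.01, 0.02 and 0.02. In KO against WT islets the short-chain acyl-CoA dehydrogenase Acads fell by -0.47 ± 0.09 and -0.46 ± 0.09 untreated and with cytokines, and turned to 0.05 with cytokines with 4 marker levels as covariates.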
